A study of Mus musculus with 4 samples.

How the data were processed

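Single-cell RNA sequencing was done on sorted CD45+ (leukocyte) cells of spinal cord from C57BL/6 mice with experimental autoimmune encephalomyelitis (EAE), a model of autoimmune inflammation of the central nervous system. Per the labels, Ctrl MO or Reg1-MOs were given by the intracranial route on day 9 after immunisation and cells were collected on day 16. MO is read here as morpholino and Reg1 as Regnase-1, the product of Zc3h12a, but the labels spell out neither and give no target site. The tissue was digested with collagenase D and passed over a Percoll density step before sorting. Libraries were made with the 10x Genomics Chromium 3' kit and sequenced on a NovaSeq, per the labels. Each of the 4 deposited matrices holds raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 5.0.1 per the file headers. The genome build was mm10 and Seurat 4.0 was used, per the submitters' processing notes, which do not state the role of Seurat. The settings of cell calling and the gene annotation release are not given in the sources used here. The matrices list 32285 genes and 29379 barcodes, with 75472324 to 174552218 UMIs per library. Gene positions were taken from GENCODE M21 on GRCm38, matched by gene identifier.

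Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 1.64% to 4.26% of the barcodes of a library. Doublets were scored per library with Scrublet in scanpy 1.11.5 (Python 3.11.15), and the cells with the highest scores were removed up to an expected rate of 0.8% per 1000 barcodes. This rule replaced the automatic threshold after that threshold had marked 251, 0, 421 and 1 cells in the 4 libraries. Counts were scaled to 10000 per cell, log-transformed and reduced to 3000 variable genes and 40 principal components without integration, and a graph of 15 neighbours was clustered by the Leiden method at resolution 1 (igraph 0.11.9, seed 0). Each of the 29 clusters was named from marker lists fixed before the data were examined. The score thresholds of the naming rule were set after the clusters had been seen, and the rule used is the second version tried, since the first left ties unnamed. Names carry the suffix "-like", because they rest on transcripts alone. The rule named 23 clusters and left 6 unnamed, with 2420 of the 26853 cells used. Unnamed clusters counted in the totals but entered no class.

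UMI counts were summed per library and class, so that each library was 1 replicate, for every class and T cell subset with at least 50 cells in each library. Genes passing filterByExpr with a minimum count of 10 were normalised by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), Reg1-MO over control, with 2 libraries per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes in the text are from edgeR unless DESeq2 is named. A set of 45 gene lists, fixed before the data were examined, was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists are from camera at the preset correlation unless stated otherwise. With 2 libraries per group, camera with an estimated correlation has few residual degrees of freedom and little power to pass a list. A list score is the mean log2 CPM of its members in a library, centred on the 4 libraries. Which list results the text describes was decided after the camera results were seen. Differences in treatment effect between classes were tested in edgeR as an interaction with the library as a block. That test was planned for microglia-like against macrophage-like cells and was added for CD4 T-like against regulatory T-like cells after their results were seen. Shares of cells were compared by a two-sided exact permutation test, whose smallest possible p with 2 against 2 libraries is 0.333. Wilson intervals (95%) cover counting error only.

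Genes named in the text were chosen by a rule fixed before the data were examined. In the 3 main classes it takes the 8 higher and 8 lower called genes with the largest fold change, a mean of at least 20 CPM and no overlap between the groups. In other classes it takes 3 each way. For each list described it adds up to 4 called members by smallest p or, where no member was called, the 2 members with the highest mean. Predicted, mitochondrial, ribosomal, hemoglobin and antigen receptor segment genes were left out. Zc3h12a was always reported. Not every gene that the rule gives is printed. Gene names outside this rule are named as such.

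The tests were tried on simulated data with the measured depths and dispersions. Changes of 4-fold were recovered for 44.0% of changed genes in microglia-like, 87.9% in macrophage-like, 94.0% in T-like and 77.6% in all cells. For 2-fold changes the recovery was 2.0%, 46.5%, 77.0% and 22.7%. In the other classes 4-fold recovery lay between 83.8% and 96.0%. The number of unchanged genes called lay between 4 and 26 per class, with 22 in regulatory T-like cells. The interaction test recovered 13.1% of 4-fold differences between microglia-like and macrophage-like cells and 87.9% between CD4 T-like and regulatory T-like cells, where it called 12 unchanged genes. Camera at the preset correlation called 0 to 3 lists per class when independent genes had no effect.

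The labels do not say whether the replicates are separate animals or pools, so each p-value measures only the spread between these samples, which may be technical. Alternatives covered DESeq2 1.42.0, its size factors in edgeR, no low-count filter, the replicate number as a block, doublets kept, a filter of at least 1000 UMIs and at most 5% mitochondrial UMIs, clustering at resolution 2, other list tests and leaving out each library in turn. When 1 library is left out, the lone sample of its group is assumed to vary like the others. A total without neutrophil-like cells was added after the shares had been seen.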

Results

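CD45+ cells of the spinal cord were profiled in 4 libraries from mice with EAE, 2 after Ctrl MO and 2 after Reg1-MOs. Reg1 is read here as Regnase-1, an RNase encoded by Zc3h12a that degrades inflammatory transcripts. The libraries held 8255 and 6765 barcodes for control 1 and 2, and 9103 and 5256 for Reg1-MO 1 and 2. Total UMI counts were 137995955 and 94577206 in the controls and 174552218 and 75472324 in the Reg1-MO libraries. The cells that passed the filters had medians of 9948 to 12103 UMIs, and 7547, 6273, 8080 and 4953 of them were used after doublets were removed. Every group value below rests on 2 libraries per group.

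Zc3h12a transcripts were measured first, in each class, as the gene that the name Reg1-MO is read to mean. No class passed the test. Zc3h12a (ENSMUSG00000042677) lies on chromosome 4, from 125118423 to 125127840 on the minus strand, with an annotated 3' UTR of 859 bases from 125118423 to 125119281. In microglia-like cells the normalised CPM (UMIs of a gene per 1e6 UMIs) were 65.1 and 132 in the controls and 60.9 and 73.4 in the Reg1-MO libraries, a log2 fold change of -0.55 ± 0.38 (SE; adjusted p = 0.963), with -0.98 without control 1 and 0.04 without control 2. In macrophage-like cells they were 48.6 and 58.4 against 49.4 and 50.4 (-0.10 ± 0.13, adjusted p = 0.684). T-like cells held 94.4 and 100.3 against 97.2 and 97.5, and all cells summed held 58.8 and 72.4 against 58.5 and 63.6. CD4 T-like cells held 108 and 119 against 106 and 113. Neutrophil-like cells held 45.2 and 41.8 against 53.7 and 58.9 (0.38 ± 0.14, adjusted p = 0.290). NK/ILC1-like cells held 104 and 95.6 against 73.5 and 100.2, and conventional dendritic cell-like cells 49.0 and 45.8 against 45.6 and 65.9. In CD8 T-like cells the counts were 55.3 and 56.5 against 72.3 and 55.5, and in regulatory T-like cells 99.2 and 87.6 against 97.5 and 90.5. The labels do not give the target site or mode of action of the Reg1-MOs, so these counts alone neither show nor exclude an effect on Regnase-1.

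**Figure D1:**
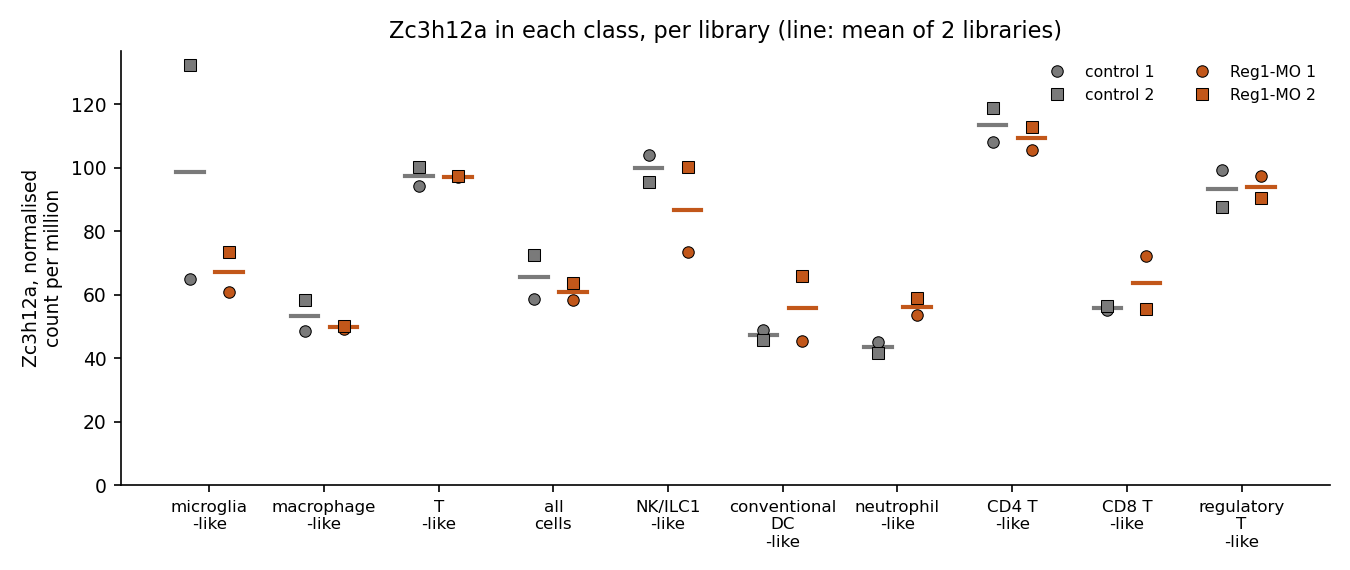
Normalised Zc3h12a CPM (vertical axis) by class; each point is 1 library (grey control, orange Reg1-MO) and each line the mean of 2 libraries. Neutrophil-like cells are the class with both Reg1-MO points, 53.7 and 58.9, above both controls, 45.2 and 41.8.

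The share of each class among all cells was compared to ask how the infiltrate differed with treatment. Neutrophil-like cells made up 29.9% ± 8.5 (SD) of the control cells and 12.0% ± 9.89 of the Reg1-MO cells. Microglia-like cells made up 8.07% ± 0.69 and 18.2% ± 4.09, a class that also held a cluster marked by Nos2 and by Arg1, a fixed monocyte/macrophage marker. Dendritic cells of 3 kinds took larger shares in both Reg1-MO libraries than in both controls. Conventional dendritic cell-like cells, which present antigen to T cells, were 1.12% ± 0.44 in controls and 3.86% ± 1.18 in Reg1-MO libraries. Plasmacytoid dendritic cell-like cells, the type I interferon producers, were 0.564% ± 0.008 and 1.73% ± 0.48, and migratory dendritic cell-like cells 0.290% ± 0.208 and 0.929% ± 0.228. B/plasma-like cells were 1.16% ± 0.05 and 0.529% ± 0.005.

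Per library, the neutrophil-like share was 23.9% in control 1 and 35.9% in control 2, against 4.98% in Reg1-MO 1 and 19.0% in Reg1-MO 2. Its 95% Wilson intervals for counting error ran from 22.9% to 24.9%, 34.7% to 37.1%, 4.52% to 5.47% and 17.9% to 20.1% in the same order. The microglia-like share was 7.58% and 8.56% against 15.3% and 21.1%. Its larger clusters each overlapped between the groups. The cluster marked by Arg1 and Nos2 (cluster 7) held 4.90% and 0.526% of all cells against 10.2% and 3.86%. The cluster marked by Sparc and P2ry12 (cluster 18) held 2.40% and 8.03% against 4.18% and 14.2%. Only the small cluster 25 did not overlap, at 0.278% and 0% against 0.891% and 3.01%. Macrophage-like cells held 25.7% and 22.7% against 32.3% and 22.9%, and T-like cells 26.1% and 16.6% against 29.5% and 22.8%. Among T-like subsets, regulatory T-like cells, which restrain immune responses, were 1.60% and 2.49% of all cells against 4.58% and 3.15%. As a share of T-like cells they overlapped between the groups, at 6.14% and 15% against 15.5% and 13.8%. CD4 T-like cells were 18.5% and 10.9% of all cells against 18.0% and 14.8%, and CD8 T-like cells 5.04% and 2.92% against 5.71% and 4.32%. NK/ILC1-like cells were 1.72% and 1.90% against 2.87% and 2.02%, and mast/basophil-like cells 0.0398% and 0.510% against 0.0371% and 0.0404%. Of the 11 classes, the unnamed cells included, 8 did not overlap between the groups, where chance gives 33.3% of classes. The shares of a library sum to a fixed total, so the classes are not independent and this count is not a test. The exact permutation p of each of these 8 was 0.33, the smallest that 2 against 2 libraries allow. Leaving out control 2 or Reg1-MO 1 brought the neutrophil-like difference from -17.9 percentage points to -11.9 or -10.9. The T-like difference of 4.79 was 9.56 without control 1, 0.0116 without control 2, 1.46 without Reg1-MO 1 and 8.11 without Reg1-MO 2. The macrophage-like difference of 3.39 was 1.86 without control 2, -1.31 without Reg1-MO 1 and 8.08 without Reg1-MO 2. With neutrophil-like cells left out of the total, an alternative chosen after the shares were seen, the macrophage-like difference was -3.49 and the T-like difference -0.52. The regulatory T-like difference of 1.82 was 1.10 without Reg1-MO 1, and the NK/ILC1-like difference of 0.635 was 0.209 without Reg1-MO 1 and 1.06 without Reg1-MO 2. The CD4 T-like difference of 1.71 was 5.48 without control 1, -2.07 without control 2, 0.0634 without Reg1-MO 1 and 3.35 without Reg1-MO 2. The CD8 T-like difference of 1.04 was 2.10 without control 1, -0.0221 without control 2, 0.344 without Reg1-MO 1 and 1.73 without Reg1-MO 2. The mast/basophil-like difference of -0.236 was -0.471 without control 1 and -0.001 without control 2.

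**Figure D2:**
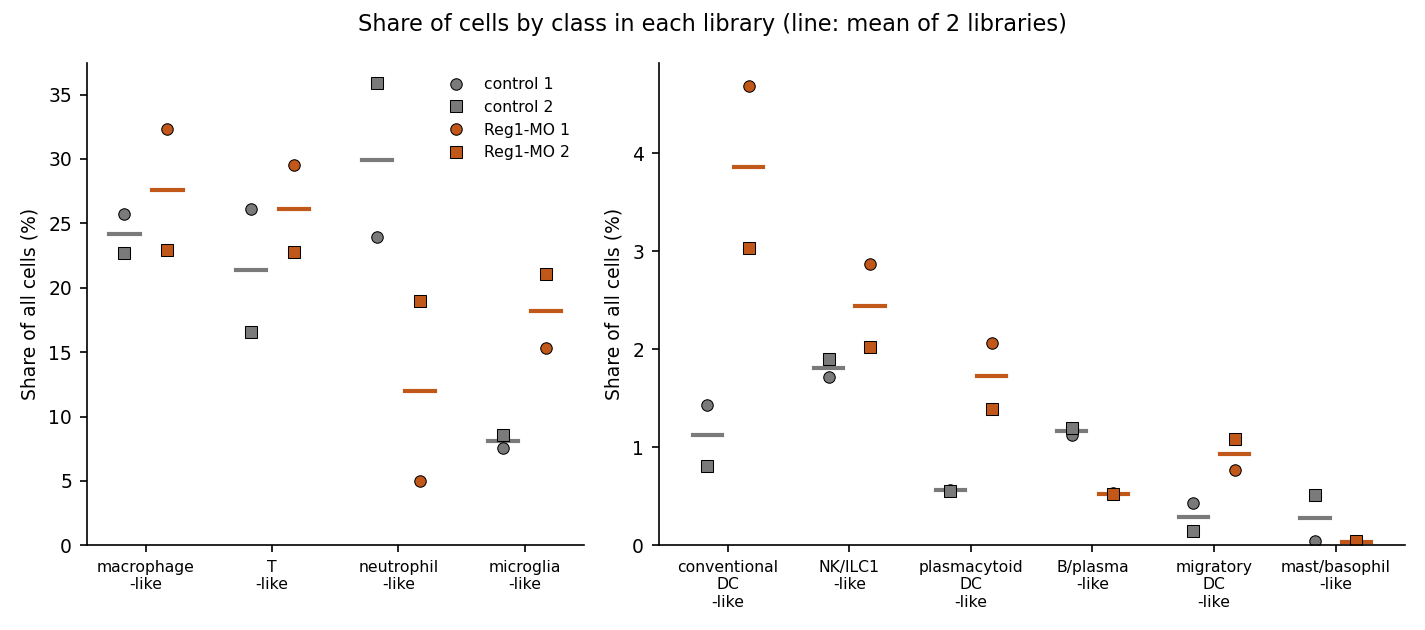
Share of all cells in percent (vertical axis) by class, larger classes on the left and smaller ones on the right; each point is 1 library and each line the mean of 2. Neutrophil-like points are lower (4.98% and 19.0% against 23.9% and 35.9%) and microglia-like points higher (15.3% and 21.1% against 7.58% and 8.56%) in the Reg1-MO libraries. The larger clusters within the microglia-like class each overlapped between the groups.

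In microglia-like cells, named for the resident macrophages of the spinal cord, several fixed gene lists moved as groups relative to the other genes. At the preset correlation 14 of the 42 lists tested passed, 11 of them upward. No member passed over all genes tested. The class also held cluster 7, marked by Nos2 and by Arg1, a fixed monocyte/macrophage marker. The share of that cluster differed between replicates, so the summed counts mix clusters in amounts that vary by library. Cell cycle genes rose, with all 18 above 0 and a median log2 fold change of 1.05 (adjusted p = 1.83e-11), as did chemokine genes (12 of 17 above 0, median 0.63, adjusted p = 4.71e-05), each with adjusted p = 0.687 with an estimated correlation. Inflammatory cytokine genes rose (11 of 13 above 0, median 0.65, adjusted p = 0.000737), and so did MHC class II genes (8 of 8 above 0, median 0.69, adjusted p = 0.00541), interferon-γ response genes (17 of 18, median 0.45, adjusted p = 0.000737) and homeostatic microglial genes (15 of 16, median 0.45, adjusted p = 0.00129), each again with adjusted p = 0.687 with an estimated correlation. Lipid export genes fell (10 of 12 below 0, median -0.64, adjusted p = 0.0038), as did disease-associated microglial genes (14 of 17 below 0, median -0.34, adjusted p = 0.0197), both with adjusted p = 0.687 with an estimated correlation. Neutrophil marker transcripts, which belong to another cell type, fell with them (12 of 12 below 0, median -1.44, adjusted p = 1.44e-07; adjusted p = 0.687 with an estimated correlation).

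The abundant members of these lists gave the following values, none past the test. Apoe, the main lipid carrier of the brain, had 9101 and 27510 CPM in the controls against 8036 and 2530 in the Reg1-MO libraries (-1.79 ± 0.84, adjusted p = 0.963), with -0.79 without control 2, -2.86 without Reg1-MO 1 and -1.15 without Reg1-MO 2. Cxcl10, a chemokine that draws T cells, had 445 and 212 against 672 and 923 (1.28 ± 0.44, adjusted p = 0.963), and Irf8, a myeloid transcription factor, 0.38 ± 0.24. The cytokine genes Il1a and Il1b had log2 fold changes of 0.90 ± 0.42 and 0.65 ± 0.57, and the microtubule regulator Stmn1 and the chromatin protein gene Hmgb2 1.12 ± 0.54 and 0.12 ± 0.32. The MHC class II genes H2-Aa and Cd74 had 0.63 ± 0.57 and 0.38 ± 0.52, the chemokine genes Ccl4 and Ccl3 0.02 ± 0.56 and -0.36 ± 0.65, and the microglial growth factor receptor gene Csf1r 0.10 ± 0.37. Fabp5, a fatty acid binding protein, had -0.27 ± 0.66 and the lysosomal protease gene Ctsd -0.34 ± 0.45. The neutrophil genes S100a8 and S100a9 had -1.47 ± 0.78 and -1.30 ± 0.84. Reported Regnase-1 target transcripts did not pass as a group (13 of 16 above 0, median 0.25, adjusted p = 0.156), with Cxcl2 at 0.14 ± 0.81 (1.84 without control 1, -0.62 without control 2) and Lcn2 at -1.63 ± 0.96 (-0.81 without Reg1-MO 1, -3.73 without Reg1-MO 2). Lcn2 also belongs to the neutrophil marker list, which fell in this class. The sign of Csf1r, Ctsd, Cd74, H2-Aa, Ifitm3, Ccl3, Ccl4, Fabp5 and Hmgb2 also changed when 1 library was left out. The type I interferon list had a median of 0.04 (adjusted p = 0.548), with Ifitm3 at 0.44 ± 0.64 and Bst2 at 0.44 ± 0.36. The log2 fold changes without control 1 were 1.64 for Il1b, 1.92 for Stmn1, 1.62 for Ifitm3, 0.86 for Bst2 and -0.83 for S100a9. Without control 2 they were 0.06 for Il1b, 0.60 for Stmn1, 0.12 for Bst2 and 0.83 for Cxcl10. Without Reg1-MO 1 they were 0.41 for Il1b, 1.35 for Il1a, 0.21 for Bst2, -0.77 for S100a8 and -0.56 for S100a9, and without Reg1-MO 2 they were 0.27 for Il1a, 0.66 for Stmn1, -2.88 for S100a8 and -2.87 for S100a9.

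No single gene passed in microglia-like cells: edgeR called 0 of 13793, with 463 at an unadjusted p under 0.05, and DESeq2 called 16. These 463 are a smaller share than that threshold gives by chance. Over all genes tested 0 members of these lists passed, and adjusted over the list alone 2 chemokine genes passed and 0 members of the other lists. Within the class, a cluster marked by Arg1 and Nos2 (cluster 7) held 64.7% and 6.15% of the control cells and 66.9% and 18.3% of the Reg1-MO cells, and a cluster marked by Sparc and P2ry12 (cluster 18) 31.6% and 93.9% against 27.3% and 67.5%. A smaller cluster marked by Ccl12 and Tmem119 (cluster 25) held 3.67% and 0% against 5.82% and 14.3%, the 1 of the 3 clusters without overlap between the groups. The replicates of a group differed in the first 2. Many list calls rested on 1 library. Without control 1 the homeostatic median was 0.17 (adjusted p = 0.659) and the neutrophil marker median -0.56 (adjusted p = 0.0892), while Regnase-1 targets passed (median 0.80, adjusted p = 0.00196), as did type I interferon genes (0.36, adjusted p = 0.0182). Without control 1 the medians were 1.80 for proliferation, 1.53 for chemokines, 1.38 for interferon-γ, 1.18 for MHC class II and -0.58 for disease-associated genes. Without control 2 the call was lost for disease-associated genes (-0.05, adjusted p = 0.803), MHC class II (0.32, adjusted p = 0.395), interferon-γ (-0.03, adjusted p = 0.823) and chemokines (0.53, adjusted p = 0.0606). Without control 2 the medians were 0.56 for proliferation, 0.25 for inflammatory cytokines and 0.78 for homeostatic genes. Without Reg1-MO 1 MHC class II (-0.03, adjusted p = 0.996) and interferon-γ genes (0.13, adjusted p = 0.446) no longer passed. The medians without Reg1-MO 1 were 0.36 for chemokines, 0.79 for homeostatic genes, -0.71 for disease-associated genes, -1.06 for lipid export and -0.78 for neutrophil markers. Without Reg1-MO 2 homeostatic (0.05, adjusted p = 0.570), disease-associated (-0.09, adjusted p = 0.323) and lipid export genes (-0.43, adjusted p = 0.248) no longer passed, and type I interferon genes passed (0.30, adjusted p = 0.0309). The medians without Reg1-MO 2 were 0.50 for proliferation, 0.27 for inflammatory cytokines, 1.16 for MHC class II, 0.78 for interferon-γ and -2.41 for neutrophil markers.

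Macrophage-like cells, the monocyte-derived phagocytes of the lesion, had higher NF-κB feedback, MHC class II, interferon and glycolysis gene lists in the Reg1-MO libraries. At the preset correlation 29 of the 42 lists tested in this class passed, 22 of them upward. Passing alone therefore does not set a list apart. Lists of lymphocyte genes passed upward too: cytotoxicity (median 1.34, adjusted p = 2.79e-05), regulatory T (0.92, adjusted p = 0.000157) and Th1 genes (0.93, adjusted p = 0.002). The Th17 list did not pass (-0.23, adjusted p = 0.152). Genes of NF-κB feedback rose, all 18 of them above 0 with a median log2 fold change of 0.89 (adjusted p = 2.79e-14; adjusted p = 0.479 with an estimated correlation). All 8 MHC class II genes were above 0 and rose as a group (median 0.96, adjusted p = 1.9e-09; 0.479 with an estimated correlation). Interferon-γ response genes (18 of 18, median 1.24, adjusted p = 3.63e-08) and type I interferon genes (19 of 19, median 0.94, adjusted p = 1.43e-06) rose (adjusted p = 0.503 and 0.511 with an estimated correlation). Glycolysis genes rose (18 of 18, median 0.84, adjusted p = 4.74e-10), as did inflammatory cytokines (12 of 13, median 0.94, adjusted p = 4.34e-06) and chemokines (12 of 16, median 0.75, adjusted p = 0.000302), each with adjusted p = 0.479 with an estimated correlation. Reported Regnase-1 targets rose as a group (14 of 16 above 0, median 0.56, adjusted p = 0.00155, and 0.479 with an estimated correlation). Icos, Ctla4 and Tnfrsf4, named here outside the rule, belong both to this list and to the regulatory T list. T cell markers also rose in this class, so transcripts carried over from T cells are not excluded for the target list. Lysosome and phagocytosis genes fell (13 of 16 below 0, median -0.33, adjusted p = 0.00338; adjusted p = 0.526 with an estimated correlation). Inflammatory monocyte genes fell too (10 of 13 below 0, median -0.50, adjusted p = 0.0126; adjusted p = 0.479 with an estimated correlation), 0 over all genes tested and 1 adjusted over the list alone, and no longer passed without control 1 (adjusted p = 0.238) or Reg1-MO 1 (adjusted p = 0.218). Lipid export genes fell (8 of 11 below 0, median -0.62, adjusted p = 0.0417; adjusted p = 0.508 with an estimated correlation), 0 over all genes tested and 2 down and 1 up adjusted over the list alone, and passed only when Reg1-MO 1 was the library left out (adjusted p = 0.0113). Oxidative phosphorylation genes did not pass (median -0.03, adjusted p = 0.892).

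Values of the abundant members follow, none past the edgeR test over all genes. Cd74, the MHC class II chaperone, had 8243 and 6379 CPM in the controls and 14040 and 13410 in the Reg1-MO libraries (0.91 ± 0.21, adjusted p = 0.240), and H2-Aa 2542 and 1909 against 4427 and 4131 (0.94 ± 0.20, adjusted p = 0.240). The cytokine gene Il1b had 2200 and 1095 against 3374 and 4472 (1.25 ± 0.37, adjusted p = 0.248), and Tgfb1 0.94 ± 0.20 (adjusted p = 0.240). The interferon-induced chemokine genes Cxcl9 and Cxcl10 had 324 and 74.9 against 952 and 705, and 356 and 53.9 against 892 and 806 (2.05 ± 0.69 and 2.05 ± 0.84). Without control 1 these were 3.47 and 3.98, and without control 2 they were 1.35 and 1.26. Nfkbia, the inhibitor of NF-κB, had 0.93 ± 0.29 and the antioxidant enzyme gene Sod2 0.85 ± 0.39. The interferon-induced genes Ifitm3 and Bst2 had 0.88 ± 0.31 and 0.69 ± 0.39. The glycolytic genes Gapdh and Pkm had 0.54 ± 0.27 and 0.46 ± 0.28, and the chemokine gene Ccl6 -0.60 ± 0.24. The Regnase-1 targets Cxcl2 and Slfn2 had 0.53 ± 0.24 and 0.23 ± 0.26, the latter -0.09 without control 2. The lysosomal protease genes Ctsd and Ctss had -1.06 ± 0.35 and -0.36 ± 0.22. With doublets kept these were -0.49 and 0.06, and with clustering at resolution 2 they were -0.12 and 0.23, so that Ctss changed sign in both. Transcripts of other cell types moved in this class too: neutrophil markers fell (10 of 12 below 0, median -0.64, adjusted p = 7e-06), with S100a8 at -0.89 ± 0.33 and S100a9 at -0.47 ± 0.50 (0.10 without Reg1-MO 1). T cell markers rose (10 of 10 above 0, median 1.32, adjusted p = 3.04e-06), at low levels, with Trbc2 at 3.44 and 1.43 against 4.89 and 10.1 CPM and Trac at 2.93 and 1.80 against 4.52 and 2.97. Both marker lists had adjusted p = 0.479 with an estimated correlation. Without control 2 the log2 fold changes were 0.83 for Il1b, 0.61 for Nfkbia, 0.38 for Sod2, 0.53 for Ifitm3, 0.23 for Bst2, 0.22 for Gapdh, 0.13 for Pkm, 0.26 for Cxcl2, -0.65 for Ctsd and 0.38 for Trac. Without control 1 they were 1.57 for Sod2, 1.34 for Ifitm3, 1.38 for Bst2, 0.96 for Gapdh, 0.90 for Pkm, 0.86 for Cxcl2, 0.64 for Slfn2, -0.25 for Ccl6, 2.35 for Trbc2 and 1.09 for Trac. Without Reg1-MO 1 they were -0.59 for Ctss, -0.49 for S100a8 and 0.31 for Trac, and without Reg1-MO 2 they were -0.15 for Ctss, -1.44 for S100a8, -1.43 for S100a9 and 0.98 for Trbc2.

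No single gene passed in macrophage-like cells: edgeR called 0 of 13259, with 2363 at an unadjusted p under 0.05, and DESeq2 called 536, with Cd74 (adjusted p = 0.000417), H2-Aa (0.000549), Tgfb1 (0.00248), Il1b (0.0117), Ctsd (0.0362) and Nfkbia (0.0382) among them. Adjusted over the list alone, 15 of 18 NF-κB feedback genes, 8 of 8 MHC class II genes, 5 of 18 glycolysis genes, 2 inflammatory cytokine genes, 1 chemokine gene and 2 T cell markers passed upward. By the same count 3 Regnase-1 targets passed upward and 1 downward, 2 neutrophil markers passed downward, and 0 members of the interferon and lysosome lists passed. Over all genes tested the count was 0 in each list. Within the class, a cluster marked by Cxcl9 and Ms4a4c (cluster 2) held 27.5% and 10.7% of the control cells and 45.9% and 56.4% of the Reg1-MO cells. A cluster marked by Gpnmb and Saa3 (cluster 11) held 23.9% and 58.5% against 17.2% and 9.52%, and a cluster marked by Vcan (cluster 8) 18.4% and 27.9% against 3.41% and 10.7%. The remaining cluster (cluster 1), which overlapped between the groups, held 30.2% and 2.95% against 33.5% and 23.3%. Values of the whole class do not separate a shift between clusters from a change within them. Control 2 stood apart in the interferon-γ list, with scores of 0.24 and -1.95 in the controls against 1.04 and 0.67. Without control 1 edgeR called 2067 genes, and without control 2 it called 39, with 0 when either Reg1-MO library was left out. Without control 1 the adjusted p was 0.0115 for Cd74, 0.00806 for H2-Aa, 0.00627 for Il1b, 0.0017 for Cxcl9, 0.000836 for Cxcl10, 0.0154 for Tgfb1, 0.0129 for Nfkbia, 0.0026 for Sod2, 0.00975 for Ifitm3 and 0.00977 for Bst2. It was 0.0139 for Gapdh, 0.0185 for Pkm, 0.0229 for Cxcl2, 0.0268 for Slfn2, 0.0270 for Ctsd and 0.0394 for Trbc2, and without control 2 it was 0.0424 for Cxcl10. Without control 2 the list medians were 0.60 for interferon-γ, 0.32 for type I interferon, 0.62 for inflammatory cytokines, 0.20 for chemokines, 0.46 for glycolysis, 0.31 for Regnase-1 targets, 0.84 for T cell markers and -0.19 for lysosome genes, each still past the test. Without control 1 they were 2.68 for interferon-γ, 2.31 for type I interferon, 1.35 for chemokines, 1.31 for glycolysis and 2.08 for T cell markers. Neutrophil markers no longer passed without Reg1-MO 1 (median -0.03, adjusted p = 0.112) and had a median of -1.74 without Reg1-MO 2. Lysosome genes no longer passed without Reg1-MO 2 (-0.17, adjusted p = 0.149) and had a median of -0.54 without Reg1-MO 1.

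**Figure D3:**
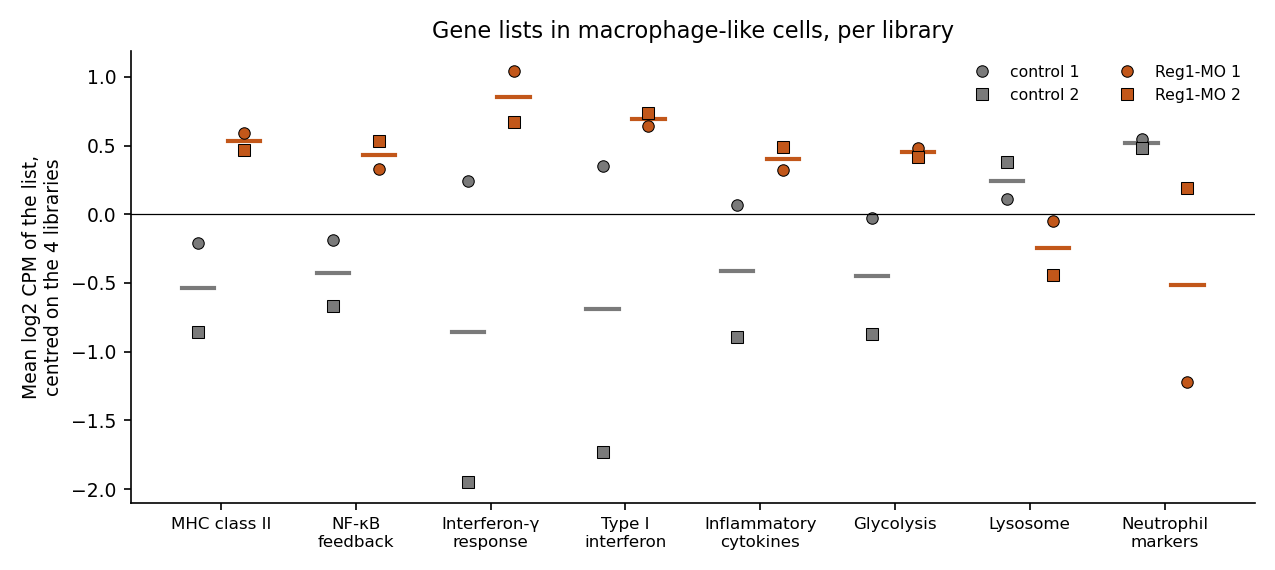
Mean log2 CPM of 8 gene lists in macrophage-like cells, centred on the 4 libraries (vertical axis); each point is 1 library and each line the mean of 2. Both Reg1-MO points lie above both controls in the first 6 lists, and control 2 lies lowest in each of them, at -1.95 in the interferon-γ list.

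Whether the treatment effect differed between microglia-like and macrophage-like cells was tested directly. No gene passed: edgeR called 0 of 14325, with 519 at an unadjusted p under 0.05 and a smallest adjusted p of 0.564. These 519 are a smaller share than the unadjusted threshold gives by chance. For Mki67, a marker of dividing cells, the effect in macrophage-like minus that in microglia-like cells was -0.62 ± 0.38 (adjusted p = 0.953), and for Ube2c, a mitotic ubiquitin enzyme, -1.49 ± 0.28 (adjusted p = 0.953). Both were named after their values were seen. Lists that passed in only one of these classes are thus not shown to differ between them.

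T-like cells as a whole had higher glycolysis genes and higher genes of the cytokines that drive EAE. At the preset correlation 21 of the 41 lists tested passed, 14 of them upward. Glycolysis genes rose (17 of 18 above 0, median 0.47, adjusted p = 7.09e-13), and so did the encephalitogenic cytokine list (8 of 9 above 0, median 0.61, adjusted p = 0.000114), each with adjusted p = 0.626 with an estimated correlation. Interferon-γ response genes rose (18 of 18, median 0.30, adjusted p = 2.08e-05; adjusted p = 0.654 with an estimated correlation), and cell cycle genes fell (11 of 18 below 0, median -0.16, adjusted p = 0.0003; adjusted p = 0.626 with an estimated correlation). The cell cycle median was 0.05 in CD4 T-like and -1.44 in regulatory T-like cells. Cycling lymphocytes formed an unnamed cluster outside this class, with 1.52% and 0.399% of all control cells against 2.10% and 1.03%. The Th1 list (median -0.26, adjusted p = 0.230), the Th17 list (-0.05, adjusted p = 0.545), the regulatory T list (0.29, adjusted p = 0.0756) and Regnase-1 targets (-0.01, adjusted p = 0.875) did not pass. Among members, none of which passed over all genes in edgeR, the lymphotoxin gene Ltb had 518 and 490 CPM in the controls and 683 and 688 in the Reg1-MO libraries (0.44 ± 0.09, adjusted p = 0.250). Ifng, which encodes interferon-γ, had 356 and 289 against 589 and 394 (0.61 ± 0.20, adjusted p = 0.341), and the glycolytic genes Ldha and Gapdh 0.57 ± 0.17 and 0.46 ± 0.16. The interferon-induced gene Irf1 had 0.36 ± 0.17, the chemokine gene Ccl5 -0.29 ± 0.12, the granule protein gene Nkg7 0.15 ± 0.11, the transcription factor genes Rora and Maf -0.25 ± 0.11 and -0.05 ± 0.22, and the receptor genes Icos and Ctla4 -0.01 ± 0.10 and 0.07 ± 0.16. The cell cycle genes Hmgb2 and Pcna had 0.07 ± 0.09 and 0.12 ± 0.13. Transcripts of other cell types moved with these lists: neutrophil markers fell (11 of 12 below 0, median -1.15, adjusted p = 6.63e-10) and microglial markers rose (9 of 10 above 0, median 0.81, adjusted p = 5.98e-06), each with adjusted p = 0.626 with an estimated correlation. Of these markers, S100a8 had -1.18 ± 0.51, S100a9 -1.12 ± 0.46 and the microglial receptor gene Cx3cr1 0.44 ± 0.19. Without Reg1-MO 1 the log2 fold changes were 0.28 for Ifng, 0.07 for Nkg7, 0.23 for Cx3cr1, -0.65 for S100a8 and -0.59 for S100a9, and without Reg1-MO 2 they were -1.98 for S100a8 and -1.92 for S100a9. Without control 2 they were 0.32 for Ldha, 0.24 for Gapdh, 0.11 for Irf1, 0.03 for Nkg7, -0.14 for Rora, 0.34 for Maf, 0.31 for Ctla4, -0.04 for Pcna, -0.45 for S100a8 and -0.59 for S100a9. Without control 1 they were 0.87 for Ldha, 0.71 for Gapdh, 0.66 for Irf1, 0.27 for Nkg7, -0.17 for Ccl5, -0.38 for Maf, -0.14 for Ctla4, 0.31 for Pcna and 0.23 for Cx3cr1.

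No single gene passed in T-like cells: edgeR called 0 of 12163, with 1546 at an unadjusted p under 0.05, and DESeq2 called 85, with Ltb (adjusted p = 0.0153) among them. Adjusted over the list alone, 12 glycolysis genes, 3 encephalitogenic cytokine genes, 4 microglial markers and 2 regulatory T genes passed upward, and 4 cell cycle genes, 3 neutrophil markers, 1 encephalitogenic cytokine gene and 1 Th17 gene passed downward. Over all genes tested the count was 0 in each list. Without control 1 edgeR called 570 genes and without control 2 it called 4. Without control 1 the adjusted p was 0.0436 for Ltb, 0.00569 for Ldha, 0.0136 for Gapdh, 0.0135 for Irf1 and 0.0387 for S100a8. Without control 2 interferon-γ genes no longer passed (median 0.10, adjusted p = 0.180), and the medians were 0.26 for glycolysis, -0.08 for cell cycle genes and -0.71 for neutrophil markers. Without control 1 the medians were 0.74 for interferon-γ, 0.74 for glycolysis and 1.48 for microglial markers. Without Reg1-MO 1 they were 0.28 for encephalitogenic cytokines, 0.39 for microglial markers and -0.62 for neutrophil markers, and without Reg1-MO 2 the neutrophil marker median was -1.99. The regulatory T list passed without control 1 (adjusted p = 0.0399, median -0.04), control 2 (adjusted p = 8.84e-12, median 0.34) or Reg1-MO 2 (adjusted p = 0.00335, median 0.27), and its direction in the test without control 1 was opposite to that with all libraries.

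Regulatory T-like cells, the Foxp3-expressing subset that restrains other T cells, had fewer cell cycle transcripts and more Ifng in the Reg1-MO libraries. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) rose from 23.7 and 28.9 CPM in the controls to 209.6 and 155 (log2 fold change 2.80 ± 0.23, adjusted p = 0.00348). The interferon-induced gene Isg15 rose from 35.5 and 23.3 to 93.4 and 132 (1.93 ± 0.26, adjusted p = 0.0302), and Cd8b1, a CD8 chain gene, from 21.9 and 14.5 to 59.8 and 49.8 (1.62 ± 0.27, adjusted p = 0.0430). All 18 cell cycle genes were below 0, and 7 fell over all genes tested, 15 adjusted over the list alone (median -1.44, adjusted p = 1.32e-35; adjusted p = 0.399 with an estimated correlation). Of them, Mki67 fell from 261 and 149 CPM to 50.8 and 61.7 (-1.88 ± 0.26, adjusted p = 0.0302), and the mitotic genes Tpx2 and Ube2c fell by 2.38 ± 0.30 and 2.36 ± 0.30 (adjusted p = 0.0302 each).

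Also in regulatory T-like cells, the tubulin regulator Stmn1 (-1.31 ± 0.16, adjusted p = 0.0302), the histone gene Hist1h2ap (-2.90 ± 0.38, adjusted p = 0.0302), the cytokinesis kinase gene Cit (-2.76 ± 0.47, adjusted p = 0.0493) and the gut homing receptor gene Ccr9 (-2.74 ± 0.45, adjusted p = 0.0430) fell. Type I interferon genes rose as a group (16 of 16 above 0, median 1.02, adjusted p = 1.2e-14; adjusted p = 0.399 with an estimated correlation), 1 over all genes tested and 11 adjusted over the list alone. So did the encephalitogenic cytokine genes (6 of 7 above 0, median 0.84, adjusted p = 9.82e-08; adjusted p = 0.399 with an estimated correlation), 1 over all genes tested and 3 adjusted over the list alone. In all, edgeR called 13 higher and 31 lower genes of 8768, against 57 by DESeq2, and 4 of the 44 were at least 10 times higher in a class outside the T-like cells. These 4, named after their values were seen, were Chil3 (-2.18, adjusted p = 0.0110) and the chemokine gene Cxcl2 (-1.24, adjusted p = 0.0365), highest in neutrophil-like cells, Cd74 (0.97, adjusted p = 0.0365), highest in conventional dendritic cell-like cells, and Mctp2 (2.18, adjusted p = 0.0357), highest in NK/ILC1-like cells. Against the other T-like subsets, a comparison added after the values were seen, 2 of the 44 were at least 10 times higher elsewhere, Cd8b1 (42.2 CPM here against 1033) and Mctp2 (19.5 against 253), both highest in CD8 T-like cells. Ifng had 131 CPM over all libraries against 531 in CD4 T-like cells, so transcripts carried over from other T cells are not excluded for these genes. Without control 1 the count was 693, and without control 2 it was 385. Cd8b1 (adjusted p = 0.123), Ccr9 (adjusted p = 0.0816) and Stmn1 (adjusted p = 0.0760) no longer passed without Reg1-MO 1, and Cit (adjusted p = 0.0511) no longer passed with RLE size factors. The type I interferon median was 1.64 without control 1 and 0.65 without control 2, and the encephalitogenic median 2.64 and 0.50.

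**Figure D4:**
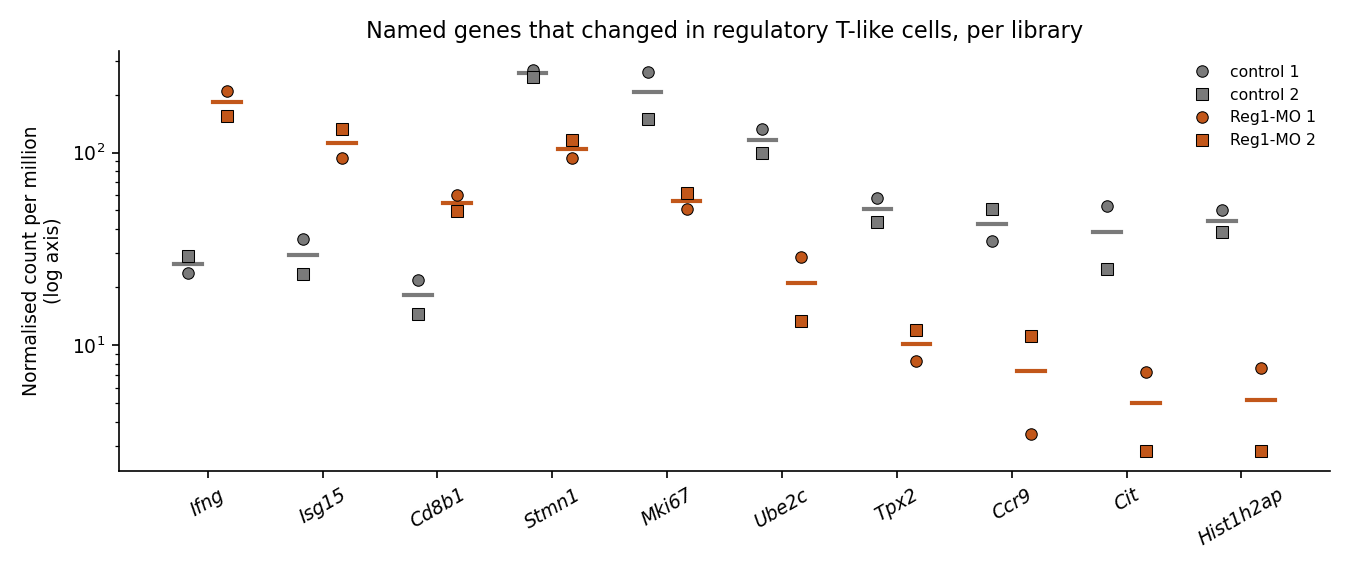
Normalised CPM (vertical log axis) of 10 named genes that changed in regulatory T-like cells; each point is 1 library and each line the mean of 2. Ifng points rise from 23.7 and 28.9 to 209.6 and 155, and Mki67 points fall from 261 and 149 to 50.8 and 61.7.

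CD4 T-like cells other than regulatory cells had a small set of changed genes. In shares worked out after these genes had been seen, their main clusters did not overlap between the groups: a cluster marked by Ccl1, Csf2, Ifng and Lta (cluster 12) held 66.4% and 68.2% of the control cells and 59.1% and 47.7% of the Reg1-MO cells, and a cluster marked by Cd40lg and Cd28 (cluster 3) 30.8% and 30.9% against 38.4% and 51.2% (permutation p = 0.33 each). The chaperone gene Hsph1 rose from 38.7 and 39.0 CPM in the controls to 85.7 and 106 (1.30 ± 0.13, adjusted p = 0.0284), the helicase gene Dhx40 from 176 and 149 to 350 and 372 (1.15 ± 0.11, adjusted p = 0.0284), the chemokine gene Ccl1 from 166 and 198 to 393 and 357 (1.05 ± 0.12, adjusted p = 0.0334) and the lymphotoxin gene Lta from 57.6 and 51.8 to 106 and 107 (0.96 ± 0.10, adjusted p = 0.0334). Encephalitogenic cytokine genes rose as a group (8 of 9 above 0, median 0.54, adjusted p = 0.000222; adjusted p = 0.605 with an estimated correlation), with Lta past the test over all genes and 4 up and 1 down adjusted over the list alone. Chil3, a chitinase-like protein gene of myeloid cells, fell (-2.44 ± 0.27, adjusted p = 0.0334), as did transcripts of neutrophil products: Lcn2 (-1.70 ± 0.17, adjusted p = 0.0284), S100a8 (-1.60 ± 0.15, adjusted p = 0.0284) and Ngp (-1.40 ± 0.12, adjusted p = 0.0284). As a list, 11 of 11 neutrophil markers were below 0 (median -1.51, adjusted p = 1.27e-30; adjusted p = 0.427 with an estimated correlation), 3 over all genes tested and 8 adjusted over the list alone. Each of these 4 genes was at least 10 times higher in neutrophil-like cells, at 140 S100a8 CPM here against 127500 there. In all, edgeR called 5 higher and 5 lower genes of 11197, against 84 by DESeq2. The count was 167 without control 1, 1 without Reg1-MO 1 and 29 without Reg1-MO 2. Without Reg1-MO 1 the adjusted p was 0.083 for Hsph1, 0.0964 for Dhx40, S100a8 and Ngp, 0.160 for Ccl1, 0.110 for Lcn2 and 0.136 for Lta, and without control 2 it was 0.0828 for Lta. The encephalitogenic median was 0.23 without Reg1-MO 1.

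Whether the treatment effect differed between CD4 T-like and regulatory T-like cells was tested directly, a test added after both results had been seen. The effect on Ifng was higher in regulatory T-like cells by 2.27 ± 0.20 on the log2 scale (adjusted p = 0.000498), and that on Ctla4, an inhibitory receptor gene, by 0.67 ± 0.09 (adjusted p = 0.0159). Of the 18 cell cycle genes 3 had a lower effect there: -1.58 ± 0.23 for the DNA topoisomerase gene Top2a (adjusted p = 0.0210), -2.67 ± 0.42 for the cell cycle kinase gene Cdk1 (adjusted p = 0.0335) and -2.85 ± 0.45 for Ube2c (adjusted p = 0.0335). The other 15 did not pass, Mki67 (-1.28 ± 0.30, adjusted p = 0.136) and Stmn1 (-1.27 ± 0.31, adjusted p = 0.146) included. In all, edgeR called 4 genes with a higher and 7 with a lower effect of 11076. The count was 36 without control 1, 17 without control 2, 89 without Reg1-MO 1 and 99 without Reg1-MO 2. Ctla4, Top2a and Cdk1 were named after their values were seen. Ifng was more abundant in CD4 T-like cells, so transcripts carried over from other T cells are not excluded for its effect.

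CD8 T-like cells, the cytotoxic subset, had higher cytotoxicity genes as a group (7 of 10 above 0, median 0.17, adjusted p = 0.0149; adjusted p = 0.555 with an estimated correlation), with the granule genes Nkg7 at 0.22 ± 0.12 and Gzma at -0.31 ± 0.54 (0.41 without Reg1-MO 2). Neutrophil markers fell (9 of 9 below 0, median -2.96, adjusted p = 2.35e-16; adjusted p = 0.555 with an estimated correlation), with S100a8 at 175 and 1157 CPM in the controls against 56.9 and 81.3 (-3.27 ± 0.73, adjusted p = 0.342) and S100a9 at -2.81 ± 0.67 (adjusted p = 0.379). Adjusted over the list alone, 3 cytotoxicity genes and 8 neutrophil markers passed, and over all genes tested 0 of either. No single gene passed: edgeR called 0 of 9712, with 793 at an unadjusted p under 0.05, and DESeq2 called 16. The count was 16 without control 1, 2 without control 2 and 1 without Reg1-MO 2, and without control 1 S100a8 (adjusted p = 0.000413) and S100a9 (adjusted p = 0.00151) passed. Cytotoxicity genes no longer passed without control 1 (median 0.34, adjusted p = 0.0976) or Reg1-MO 1 (0.31, adjusted p = 0.677), and had a median of 0.28 without Reg1-MO 2. Without control 2 the neutrophil marker median was -1.30, with S100a8 at -1.38 and S100a9 at -1.13, and Nkg7 at 0.12.

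NK/ILC1-like cells, innate cytotoxic lymphocytes, had higher interferon-induced genes in the Reg1-MO libraries. Of the type I interferon list, Xaf1 rose from 17.0 and 11.5 CPM to 48.8 and 37.6 (1.62 ± 0.33, adjusted p = 0.0147) and Irf7 from 20.4 and 24.2 to 66.5 and 39.0 (1.33 ± 0.31, adjusted p = 0.0327). At low control levels, Isg15 rose from 5.66 and 10.2 to 32.3 and 26.45 (1.93 ± 0.42, adjusted p = 0.0229). Ifit3 rose from 3.40 and 1.27 to 19.6 and 13.9 (2.81 ± 0.62, adjusted p = 0.0243). All 11 measured members were above 0, 4 past the test over all genes and 6 adjusted over the list alone (median 0.81, adjusted p = 1.85e-09; adjusted p = 0.597 with an estimated correlation). Other genes that rose were Cxcl10 from 14.7 and 6.37 to 67.2 and 61.3 (2.58 ± 0.34, adjusted p = 0.000214), the secreted phosphoprotein gene Spp1 (2.71 ± 0.49, adjusted p = 0.00469), and the MHC class II genes Cd74 (1.63 ± 0.31, adjusted p = 0.00728) and H2-Ab1 (2.14 ± 0.42, adjusted p = 0.0110). MHC class II genes rose as a list (5 of 5 above 0, median 1.57, adjusted p = 1.99e-06; adjusted p = 0.597 with an estimated correlation), 2 over all genes tested and 4 adjusted over the list alone. Chil3, a chitinase-like protein gene of myeloid cells, fell (-2.49 ± 0.28, adjusted p = 6.72e-05), as did the neutrophil transcripts Retnlg (-4.08 ± 0.59, adjusted p = 0.000751), Lcn2 (-2.31 ± 0.41, adjusted p = 0.00397) and S100a9 (-1.24 ± 0.26, adjusted p = 0.0153). The neutrophil list had 7 of 7 below 0 (median -1.41, adjusted p = 1.51e-12; adjusted p = 0.597 with an estimated correlation), 3 over all genes tested and 6 adjusted over the list alone.

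Of the 90 genes edgeR called in NK/ILC1-like cells, 44 higher and 46 lower of 7710, 11 were at least 10 times higher in another class, among them Cd74, H2-Ab1 and Isg15, highest in conventional dendritic cell-like cells, Cxcl10, highest in microglia-like cells, Spp1, highest in macrophage-like cells, and Chil3, Lcn2, Retnlg and S100a9, highest in neutrophil-like cells. Cd74 had 107 CPM here against 22170 in conventional dendritic cell-like cells. DESeq2 called 26 genes, with S100a9 not among them (adjusted p = 0.403). The count was 218 without control 1 and 142 without control 2. Without Reg1-MO 1 the adjusted p was 0.539 for H2-Ab1 (log2 fold change 1.22), 0.451 for Cd74 (0.68), 0.215 for Xaf1, 0.339 for Isg15 and 0.570 for Irf7 (0.82). Without control 1 it was 0.0804 for Isg15 and 0.0750 for Irf7, and without control 2 it was 0.122 for Ifit3, 0.0898 for Lcn2 and 0.0594 for S100a9 (-0.59), with Retnlg at -2.17. With doublets kept, Retnlg (-0.91, adjusted p = 0.450), Chil3 (-1.21, adjusted p = 0.176) and S100a9 (-0.37, adjusted p = 0.699) no longer passed. The MHC class II list no longer passed without Reg1-MO 1 (median 0.47, adjusted p = 0.0918). The type I interferon median was 1.56 without control 1 and 1.29 without Reg1-MO 2, and the neutrophil marker median -0.74 without control 2 and -2.23 without Reg1-MO 1.

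Conventional dendritic cell-like cells had higher interferon-γ response genes (17 of 17 above 0, median 1.18, adjusted p = 1.67e-13) and inflammatory cytokine genes (11 of 11 above 0, median 1.00, adjusted p = 1.21e-09), each with adjusted p = 0.388 with an estimated correlation. Among these, Il1b had 1399 and 1224 CPM in the controls against 2143 and 2746 (0.90 ± 0.17, adjusted p = 0.182), Tgfb1 0.44 ± 0.18 and the dendritic cell transcription factor gene Irf8 0.54 ± 0.16. Neutrophil markers fell (11 of 12 below 0, median -4.77, adjusted p = 6.37e-28; adjusted p = 0.388 with an estimated correlation), with S100a8 at 1529 and 5443 against 36.9 and 140 (-5.33 ± 0.83, adjusted p = 0.158) and S100a9 at -4.76 ± 0.85 (adjusted p = 0.180). Adjusted over the list alone, 6 members of each inflammatory list and 11 neutrophil markers passed, and over all genes tested 0. No single gene passed: edgeR called 0 of 9756, with 1308 at an unadjusted p under 0.05, and DESeq2 called 83, S100a8 (adjusted p = 0.00266), S100a9 (adjusted p = 0.0153) and Il1b (adjusted p = 0.0104) among them. The count was 1258 without control 1, 324 without control 2, 27 without Reg1-MO 1 and 10 without Reg1-MO 2. The adjusted p of S100a8 was 1.21e-11, 1.02e-10, 0.0257 and 0.0182 in the same order, and that of S100a9 2.89e-09, 2.78e-08, 0.0208 and 0.00969. With doublets kept S100a8 had -2.07 (adjusted p = 0.335) and S100a9 -1.89 (adjusted p = 0.343). Il1b passed without control 1 (adjusted p = 0.000366), control 2 (adjusted p = 0.00486) or Reg1-MO 1 (adjusted p = 0.0487), and Irf8 (adjusted p = 0.0215) passed without control 1. The interferon-γ median was 2.39 without control 1 and 0.65 without control 2, and Tgfb1 had 0.28 without Reg1-MO 2.

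Neutrophil-like cells, although fewer, had higher interferon-induced genes, but those named here were more abundant in microglia-like cells. Ifi27l2a rose from 78.0 and 41.7 CPM to 220.5 and 259.5 (2.01 ± 0.27, adjusted p = 0.0497) and the DNA sensor gene Ifi204 from 7.98 and 5.60 to 24.8 and 22.9 (1.81 ± 0.21, adjusted p = 0.0316). The type I interferon list rose (17 of 18 above 0, median 1.23, adjusted p = 1.14e-18; adjusted p = 0.414 with an estimated correlation), with 1 member past the test over all genes and 15 adjusted over the list alone. The transcription factor gene Trps1 (1.51 ± 0.21, adjusted p = 0.0497) and the sialyltransferase gene St8sia4 (1.42 ± 0.16, adjusted p = 0.0298) rose, and the prion protein gene Prnp fell (-2.17 ± 0.26, adjusted p = 0.0316). Genes that mark other classes rose with them: MHC class II genes (8 of 8 above 0, median 2.45, adjusted p = 5.71e-09; adjusted p = 0.467 with an estimated correlation), with Cd74 at 61.1 and 54.0 against 611.5 and 112, and microglial markers (10 of 11 above 0, median 1.36, adjusted p = 1.21e-09; adjusted p = 0.405 with an estimated correlation), with P2ry12 at 0.76 ± 0.24. Of these, 7 MHC class II genes and 7 microglial markers passed adjusted over the list alone and 0 over all genes tested, H2-Aa at 2.62 ± 0.67 (adjusted p = 0.157) and Cd74 at 2.63 ± 0.62 (adjusted p = 0.141) included. In all, edgeR called 11 higher and 4 lower genes of 10607, against 146 by DESeq2, and 5 of the 15, Ifi204 among them, were at least 10 times higher in another class. Ifi27l2a was 8.58 times higher in microglia-like, Trps1 7.07 times in macrophage-like and St8sia4 4.92 times in NK/ILC1-like cells. Transcripts carried over from other classes are therefore not excluded for these higher genes. The count was 283 without control 1, 105 without control 2, 564 without Reg1-MO 1 and 185 without Reg1-MO 2. Ifi27l2a and Trps1 no longer passed with RLE size factors (adjusted p = 0.0506 each). Cd74 and H2-Aa passed when any 1 library was left out, with log2 fold changes of 0.96 and 0.78 without Reg1-MO 1 (adjusted p = 0.00383 and 0.0171). With doublets kept they had 0.43 and 0.66 (adjusted p = 0.714 and 0.558). The adjusted p was 1.91e-14 and 4.42e-18 without control 1, 2.73e-12 and 3.53e-15 without control 2, and 7.5e-07 for both without Reg1-MO 2. The MHC class II median was 0.84 without Reg1-MO 1, and the type I interferon median 0.78 without control 2 and 0.80 without Reg1-MO 2.

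All cells summed per library show composition and expression together. Homeostatic microglial genes rose (16 of 16 above 0, median 1.07, adjusted p = 2.1e-17; adjusted p = 0.586 with an estimated correlation), 14 of them adjusted over the list alone, with the growth factor receptor gene Csf1r at 408 and 406 CPM in the controls against 602 and 665 (0.64 ± 0.14, adjusted p = 0.205). Neutrophil markers fell (12 of 12 below 0, median -1.40, adjusted p = 2.95e-05; adjusted p = 0.643 with an estimated correlation), 0 of them adjusted over the list alone, with S100a8 at 18650 and 33940 against 2733 and 14900 and S100a9 at 20070 and 31220 against 2842 and 17560. Oligodendrocyte markers rose as a group (6 of 8 above 0, median 1.35, adjusted p = 3.82e-09; adjusted p = 0.586 with an estimated correlation), 6 adjusted over the list alone, while the myelin genes with the highest counts, Mbp and Cnp, had -0.09 ± 0.13 and 0.62 ± 0.20. Over all genes tested no member of these lists passed. No single gene passed: edgeR called 0 of 16780, with 2891 at an unadjusted p under 0.05, and DESeq2 called 1021, with Csf1r (adjusted p = 0.00141) among them. The count was 3 without Reg1-MO 1 and 37 without Reg1-MO 2. The neutrophil marker median was -0.64 without Reg1-MO 1 and -3.23 without Reg1-MO 2, with S100a8 at -0.78 and -3.26 and S100a9 at -0.51 and -3.17. Without control 2 Cnp had 0.38 and Mbp 0.03.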

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

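The test of CD4 T-like against regulatory T-like cells and both tests of the cell cycle pattern were chosen only after the results they bear on were seen.

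Cells with at least 20 UMIs of oligodendrocyte markers numbered 11 in Reg1-MO 1 and 5 in Reg1-MO 2, against 3 in each control, a signal of transcripts that mark none of the report's classes. The sort for CD45 would remove oligodendrocytes themselves. That is 0.136% and 0.101% of the cells against 0.0398% and 0.0478%, and 3 and 1 of the Reg1-MO cells lay in the mixed cluster led by granulocyte progenitor genes.

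The test called 11 genes as differing in treatment effect between CD4 T-like and regulatory T-like cells. Over all libraries Ifng and Il22 were 4.05 and 3.98 times higher in CD4 T-like than in regulatory T-like cells. Mctp2 was 13 times higher in CD8 T-like cells, so transcripts carried over from other T cells are not excluded for these genes. Top2a, Cks1b, Ube2c and H2afx were not higher in another T-like subset. The effect was higher in regulatory T-like cells for Ifng, the inhibitory receptor gene Ctla4, the calcium-binding membrane protein gene Mctp2 (2.31 ± 0.32, adjusted p = 0.0159) and Il22, a cytokine gene listed at 0 in both controls there. It was lower for the cell cycle genes Top2a, Cdk1, Cks1b (-1.81 ± 0.29, adjusted p = 0.0335) and Ube2c, the histone gene H2afx (-1.73 ± 0.22, adjusted p = 0.0159), the tubulin gene Tuba1b (-1.19 ± 0.16, adjusted p = 0.0159) and the potassium channel gene Kcnq5 (-1.17 ± 0.19, adjusted p = 0.0335). The count was 36 without control 1, 17 without control 2, 89 without Reg1-MO 1 and 99 without Reg1-MO 2.

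The lower cell cycle transcripts of regulatory T-like cells were weighed against 2 technical explanations. Cycling regulatory T cells placed in another cluster would leave all Foxp3-expressing cells alike, but over cells with a Foxp3 UMI in the T-like clusters and the cycling cluster the log2 ratio of Reg1-MO to control was -1.05, with 3619 and 1929 CPM in the controls and 1490 and 1193 in the Reg1-MO libraries. A Foxp3 UMI was present in 79.3% to 83.3% of regulatory T-like cells per library, in 0.146% to 0.547% of CD4 T-like cells, and in 5 and 0 cells of the cycling cluster in the controls against 5 and 0 in the Reg1-MO libraries. Of the Foxp3 cells, 96 of 106 and 128 of 130 in the controls were regulatory T-like, as were 294 of 308 and 130 of 135 in the Reg1-MO libraries. The ratio therefore mostly restates that class. Free RNA from cycling cells would lower the same genes in CD4 T-like cells, where their median was 0.05 against -1.44 in regulatory T-like cells. These values argue against free RNA, and against misplaced cycling cells only as far as a Foxp3 UMI marks them. A lower rate of division among regulatory T-like cells after Reg1-MOs is a hypothesis that stays open, since it was found and tested on the same cells.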

How the results depend on the processing

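The interaction of CD4 T-like with regulatory T-like cells, the total without neutrophil-like cells and, outside the 3 main classes and all cells, the counts with no low-count filter, other size factors, doublets kept, a stricter filter or finer clusters were chosen only after the data had been seen.

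Zc3h12a kept its side of the threshold in all 97 alternatives over 10 classes, with log2 fold changes from -0.98 to 0.47 and a smallest adjusted p of 0.105, and its sign differed in 16. Of 1057 alternatives for named genes, 966 kept their side of the threshold, 28 no longer passed, 63 newly passed and 0 were called in the opposite direction. The sign differed in 33. Of 357 for gene lists, 244 kept their side of the threshold, 107 no longer passed and 6 newly passed, and the direction of the test differed in 10. Of 99 counts of changed genes 52 moved by over 1.5 times, as did 22 of 70 counts of lists and 4 of 10 counts of the interactions. Of 123 shares 109 stayed within the spread between replicates or kept their test result. For 52 of these, with 1 library left out, that outcome was fixed in advance. With 2 libraries per group the shift cannot exceed the spread used as the bound. Some of these differences still changed sign, the macrophage-like and CD4 T-like ones included.

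DESeq2 called 16 genes in microglia-like, 536 in macrophage-like, 85 in T-like, 1021 in all cells, 26 in NK/ILC1-like, 83 in conventional dendritic cell-like, 146 in neutrophil-like, 84 in CD4 T-like and 16 in CD8 T-like cells. With no low-count filter edgeR called 51 in microglia-like, 2047 in macrophage-like, 634 in T-like, 215 in all cells, 188 in NK/ILC1-like, 751 in conventional dendritic cell-like, 628 in neutrophil-like, 642 in CD4 T-like, 216 in CD8 T-like and 383 in regulatory T-like cells. With the replicate block it called 31 in all cells, 21 in conventional dendritic cell-like, 526 in neutrophil-like, 16 in CD4 T-like, 1 in CD8 T-like and 262 in regulatory T-like cells, and camera 23 lists in microglia-like cells. Among named genes Cd74 and H2-Aa in neutrophil-like cells (adjusted p = 7.07e-19 and 5.7e-22) and S100a8 and S100a9 in conventional dendritic cell-like cells (5.23e-05 and 0.000204) newly passed with the block. The replicate number is only a hint of pairing: the correlation of libraries with the same number ran from -0.032 in CD8 T-like to 0.437 in microglia-like cells. With the stricter cell filter edgeR called 1 gene in all cells and 69 in neutrophil-like cells, where it called 52 with doublets kept. The cause of these differences was not tested.

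At the preset correlation camera called 14 of 42 lists in microglia-like, 29 of 42 in macrophage-like and 21 of 41 in T-like cells. It called 15 of 36 in NK/ILC1-like, 25 of 39 in conventional dendritic cell-like and 17 of 38 in neutrophil-like cells. For CD4, CD8 and regulatory T-like cells the counts were 21 of 40, 15 of 40 and 18 of 39, and for all cells 20 of 45. With an estimated correlation camera called 0 lists, and fry called 0 lists, in each of the 10 classes. Camera estimates how closely the genes of a list move together, which the preset of 0.01 does not. With 2 libraries per group the estimated version had little power, so its counts of 0 do not decide whether a list moved.

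Leaving out 1 library at a time gave 0 to 2067 genes in macrophage-like, 0 to 570 in T-like, 0 to 37 in all cells, 66 to 218 in NK/ILC1-like, 10 to 1258 in conventional dendritic cell-like, 105 to 564 in neutrophil-like, 1 to 167 in CD4 T-like, 0 to 16 in CD8 T-like and 36 to 693 in regulatory T-like cells. The interaction of CD4 T-like with regulatory T-like cells gave 17 to 99, and the lists in NK/ILC1-like cells 7 to 17.

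The B/plasma-like difference in share was -0.719 percentage points with doublets kept, -0.569 with the stricter filter and -1.07 without neutrophil-like cells in the total. The macrophage-like difference was 9.69 with doublets kept and -3.49 without neutrophil-like cells in the total, and the NK/ILC1-like difference 0.145. In that total T-like cells made up 34.3% and 25.9% of the controls and 31.0% and 28.2% of the Reg1-MO libraries. An edgeR test of cell counts gave log2 fold changes of -1.13 for B/plasma-like and 1.62 for plasmacytoid dendritic cell-like cells (adjusted p = 0.0436 each, and 0.0602 and 0.0217 with the replicate block). With the replicate block it gave 1.80 for conventional, 1.60 for plasmacytoid and 1.69 for migratory dendritic cell-like, 1.16 for microglia-like, -1.59 for neutrophil-like and -2.31 for mast/basophil-like cells (adjusted p from 0.0205 to 0.0349, against 0.0436 to 0.228 without the block). Classes with under 50 cells in a library under an alternative gave no value there. Recovery was lowest in the microglia-like class, where 4-fold changes were recovered for 44.0% of simulated genes.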

Other observations

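Of the tests in this part, those of carried-over marrow cells, free RNA and doublets were chosen only after the results were seen.

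Some clusters carried no class name and entered no comparison of expression. A mixed cluster, led by Elane, Mpo and Prtn3, the granule genes of granulocyte progenitors, but also by the hemoglobin gene Hbb-bs, made up 3.56% and 3.71% of the control cells and 0.842% and 1.74% of the Reg1-MO cells. Its cells with at least 20 UMIs of Elane, Mpo, Prtn3 and Ctsg made up 2.66% and 2.44% against 0.446% and 0.808%. Cells marked by Acod1, Cxcl3 and Cxcl2, genes of activated myeloid cells, made up 3.55% and 2.20% against 0.928% and 1.86%. Cycling lymphocytes marked by Gzma, Mki67 and Top2a made up 1.52% and 0.399% against 2.10% and 1.03%, and macrophages marked by Ms4a7 and Ccl8 1.35% and 0.0956% against 1.92% and 0.909%. Cells marked by Saa3, Apoe and Gpnmb came almost wholly from control 2, with 20 and 267 cells in the controls and 3 in each Reg1-MO library. Gamma delta T-like cells, innate-like T cells, made up 1.02% and 0.255% against 1.14% and 0.586%.

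The lower share of neutrophil-like cells was weighed against 2 technical explanations. Loss of low-RNA barcodes is argued against, since among cells with at least 5000 UMIs the difference was still -15.7 percentage points, with 18.6% and 28.7% in the controls and 2.63% and 13.2% in the Reg1-MO libraries. Bone marrow cells carried over in different amounts would move immature and mature granulocytes together, and the ratio of immature to mature cells in Reg1-MO over control libraries was 0.88 (0.52 and 0.42 against 0.50 and 0.33), or 0.79 with only the cells of the mixed progenitor cluster that held at least 20 granule gene UMIs and 0.82 without that cluster. Carry-over therefore may account for the pattern. A fall across all granulocyte stages after Reg1-MOs allows the same ratio and stays open.

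The lower neutrophil transcripts in CD4 T-like and NK/ILC1-like cells were weighed against 2 technical explanations, doublets and free RNA. Doublets with neutrophils are argued against in CD4 T-like cells, where the top 1% of cells held a median of 10.6% of the S100a8 and S100a9 UMIs, but stay open in NK/ILC1-like cells, where it was 33.3% with 63.2% in both control 2 and Reg1-MO 1. Free RNA would keep the proportions of neutrophil transcripts, and the SD over 7 genes of the log2 ratio to neutrophil-like cells had a median of 0.72 in CD4 T-like cells (0.81, 0.63, 1.02 and 0.63 per library), under the bound of 0.75, and of 0.99 in NK/ILC1-like cells, between the bounds of 0.75 and 1.5. The 7 genes were picked from these same results, as lower calls in either class that were at least 10 times higher in neutrophil-like cells. Chil3 comes from other cells too, and 2 libraries lay above the bound in CD4 T-like cells. The SD therefore cannot decide whether free RNA contributes in CD4 T-like cells. S100a8 there (195, 247.9, 65.9 and 82.9 CPM) kept the library order of all cells (18230, 32760, 2728 and 15810 CPM) but was not proportional to it. An S100a8 or S100a9 UMI was present in most CD4 T-like cells, 89.3% and 94.3% in the controls against 57.7% and 74.7%. In NK/ILC1-like cells these shares were 89.2% and 91.6% against 65.5% and 76.0%. A biological loss of these transcripts in lymphocytes was not tested.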
